A study of Mus musculus with 5 samples.

How the data were processed

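Bulk RNA-seq was analysed from mature CD8 single-positive thymocytes of mice that were purified by flow cytometry. Per the labels' protocols, total RNA was extracted with a column kit, samples were kept by RNA integrity, and libraries were made from a small amount of total RNA with the NEBNext RNA Library Prep Kit. The genotype label grouped the samples into Runx3 +/+ (n = 2) and Runx3 +/WRPW (n = 3), and the replicate numbers of the labels name the libraries. The column header of the file for Runx3 +/+ library 2 bears the number 3, and that of Runx3 +/WRPW library 2 is a general name of an aligner; the assignment followed the sample records.

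The deposited values are raw counts of reads per gene symbol for 35976 genes, 1 file per sample, with no normalization by the authors. Per the submitters' processing notes, cutadapt 4.0, HISAT2 2.2.1, featureCounts 2.0.8 and edgeR 3.36.0 were used with the mm10 genome. The notes give no settings, so the annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads shared between near-identical genes could have been left out by such counting, which would lower genes with many processed pseudogenes, and without strand a gene and an overlapping antisense gene cannot be told apart. Every row names a gene, so none was left out of the library totals.

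Gene names and coordinates came from RefSeq for GRCm38.p6, the assembly that mm10 names, and exon lengths, overlaps and GC content from GENCODE M21 on the same assembly, with 32501 rows matched to RefSeq by symbol and 1005 by an older symbol (93.1% in all). Libraries were compared before they were averaged; the smallest chi-square per gene between any pair was 16.5, so no pair agreed within sampling noise. Total counts ran from 15715242 to 43758550, and 3 counts, the floor used for a gene with none, correspond to 0.0686 to 0.191 CPM per library. The intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

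The contrast of Runx3 +/WRPW with Runx3 +/+ was tested with edgeR 4.0.16 in R 4.3.3 (TMM factors of 0.981 to 1.034, filterByExpr with a minimum count of 10, glmQLFit and glmQLFTest), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The filter left 13666 genes. The fit had a common biological coefficient of variation of 0.211 and 3.16 prior degrees of freedom. Log2 fold changes are Runx3 +/WRPW over Runx3 +/+ as fitted, the standard error is the absolute log2 fold change divided by the square root of F, and levels are TMM-scaled CPM with the SD between libraries. Fold values are from the fit except where a ratio of counts is named.

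The 21 gene lists, the test of the contrast, the alternatives and the rule for named genes were chosen before the data were examined; the lists and tests chosen later are named with the other observations. Of 21 lists, drawn from textbook knowledge and holding 294 genes, 6 genes had no row in the files. The 18 lists with at least 3 tested members were tested with camera in limma 3.58.1 (preset correlation 0.01), while the natural killer and erythroid lists had too few and the sex-linked list is given as levels. The direction of camera follows the moderated statistics of the members, so it can differ in sign from their median or mean log2 fold change. Camera with a correlation estimated from the residuals and fry were alternatives. The named genes are Runx3, Runx1, Cbfb, Cd4, Cd8a, Cd8b1, Zbtb7b and Itgae; the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 1 and no overlap between the genotypes, predicted models and receptor segments left out; and up to 4 called members per list with the smallest p-values, or at most 2 given as values where a list had none. A further 14 genes were chosen after their values were seen: Cxcr5, Ccr7, Socs3, Bcl2, and the called members of the Bcl-2 and TGF-beta superfamilies given among the other observations.

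The pipeline was tested on simulated data with the means and library sizes of these samples, 13424 genes in the fit and 2 groups of the same sizes. Among changed genes it recovered 28.6% at 1.5-fold, 56.0% at 2-fold, 69.4% at 4-fold and 81.6% at 8-fold, and 11 of 147 calls (7.48%) were false. Only 49 or 50 genes were changed at each fold, beside 2 lists of changed genes. That is a smaller share of genes than was called in the data (13.6%), which makes the adjusted cutoff stricter. These recoveries therefore need not hold for the data. Of the simulated lists, both changed ones and 0 of the other 18 were called. Their genes were drawn independently of each other, so these calls cannot show how camera does on lists with correlated members. Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no low-count filter, a stricter filter of 1 CPM in every library of a genotype, robust dispersion estimates, a minimum fold of 1.2 in glmTreat, the replicate number as a block, sex-linked and chromosome Y genes left out, and each library left out in turn.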

Results

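RNA was sequenced from sorted mature CD8 single-positive (SP) thymocytes, the cells of the CD8 T cell lineage that are about to leave the thymus. Of the 5 libraries, 2 came from wild-type mice (Runx3 +/+) and 3 from mice with 1 copy of an allele named WRPW (Runx3 +/WRPW). Total counts were 21635675 and 25526389 in the Runx3 +/+ libraries and 43758550, 15715242 and 21857093 in Runx3 +/WRPW libraries 1, 2 and 3. The labels do not say that the samples of a genotype came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Transcripts of the Y-linked gene Ddx3y stood at 247 to 355 CPM in all 5 libraries and Xist at no more than 0.690 CPM. A count was present at 27414 genes in Runx3 +/WRPW library 2, against 17237 to 18967 genes in each of the other 4 libraries. The correlation of log2 CPM across genes was 0.979 between the Runx3 +/+ libraries, 0.988 between Runx3 +/WRPW libraries 1 and 3, and 0.969 to 0.970 between library 2 and those. Genes are not independent replicates. In a principal component analysis, the first component held 53.2% of the variance and separated the genotypes, and the second, with 25.5%, set Runx3 +/WRPW library 2 apart. On the first component this library also lay further out, at 54.7 against 26.4 and 23.8 for Runx3 +/WRPW libraries 1 and 3. The share of the first component is therefore not a measure of genotype alone.

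The comparison asked which transcripts of mature CD8 SP thymocytes differ when 1 of the Runx3 alleles is WRPW. Runx3 is the Runt-domain transcription factor that silences Cd4 and sustains the CD8 lineage programme. As background, Runx proteins end in a VWRPY motif that binds Groucho/TLE corepressors, and WRPW is the TLE-binding motif of the Hes repressors. Transcripts of Runx3 itself (chromosome 4, 135120645 to 135177990, mm10) were at 273 and 357 CPM in the Runx3 +/+ libraries and at 394, 341 and 422 CPM in the Runx3 +/WRPW libraries. The log2 difference of 0.29 ± 0.14 (SE) did not pass edgeR's quasi-likelihood test (adjusted p = 0.234), and it was 0.08 without Runx3 +/+ library 1 and 0.49 without Runx3 +/+ library 2. The count per gene does not show which allele was present, so the genotype labels were not checked by it. Runx1 (chromosome 16, 92601466 to 92826074), the family member of earlier thymocytes, was lower by 3.92-fold, from 72.6 ± 26.7 CPM (SD, n = 2) to 18.7 ± 5.0 CPM (SD, n = 3), with an adjusted p = 0.00963 in the edgeR test. Without Runx3 +/+ library 2 that call was lost. Transcripts of Cbfb, the shared partner of the Runx proteins, were at 297 ± 25 CPM in Runx3 +/+ and 231 ± 16.9 CPM in Runx3 +/WRPW, just short of the threshold (adjusted p = 0.0505).

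In Runx3 +/WRPW cells, 23 of 26 tested cell-cycle genes fell (camera adjusted p = 0.0611 with an estimated correlation), 8 of 19 maturation and egress genes fell with 2 higher, and 4 of 13 innate-like or memory CD8 genes rose. With an estimated correlation camera gave these last lists an adjusted p = 0.368 and an adjusted p = 0.379. Itgae (chromosome 11, 73090505 to 73147449), which encodes the integrin CD103, was 13.9-fold lower, from 799 ± 106 CPM (SD, n = 2) to 57.2 ± 6.84 CPM (SD, n = 3; edgeR adjusted p = 0.000189). S1pr1 (chromosome 3, 115710433 to 115715055), the sphingosine-1-phosphate receptor by which thymocytes leave the thymus, was 12.8-fold lower, from 317 ± 57.8 to 24.7 ± 5.75 CPM (adjusted p = 0.00089). Mki67 (chromosome 7, 135689784 to 135716450), a marker of dividing cells, was 7.85-fold lower, from 249 ± 6.79 to 31.8 ± 1.33 CPM (adjusted p = 5.19e-05). Eomes (chromosome 9, 118478186 to 118486132), a T-box factor of memory CD8 T cells, was 9.37-fold higher, from 11.1 ± 1.70 to 105 ± 39.4 CPM (adjusted p = 0.00402). Ccr8 (chromosome 9, 120092133 to 120094906), a chemokine receptor gene, was 21.6-fold higher, from 5.0 ± 2.04 to 107 ± 20.5 CPM (adjusted p = 0.0012). Of the 13666 genes tested, 1855 (13.6%) changed, with 853 higher and 1002 lower in Runx3 +/WRPW. At least a 2-fold change was seen in 315 of the higher and 367 of the lower genes, and at least a 4-fold change in 141 and 151. The total was 542 without Runx3 +/+ library 1, 277 without Runx3 +/+ library 2, 768 without Runx3 +/WRPW library 1 and 950 without Runx3 +/WRPW library 3, with the lone Runx3 +/+ library of the first pair of fits assumed to vary like the other genotype. It was 1431 without Runx3 +/WRPW library 2, the one with counts at many more genes. The fits without Runx3 +/+ library 1 or 2 tested 18369 and 18169 genes, so their totals rest on more tests than the 13666 with all libraries. Of the 85 named genes that passed, 37 lost their call without Runx3 +/+ library 1 (among them Eomes, Cxcr3, Il18rap and Foxp3). The number lost was 51 without Runx3 +/+ library 2 (among them Runx1, Eomes, Klf2 and Lef1), and 17, 6 and 14 without Runx3 +/WRPW libraries 1, 2 and 3. None changed sign.

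**Figure D1:**
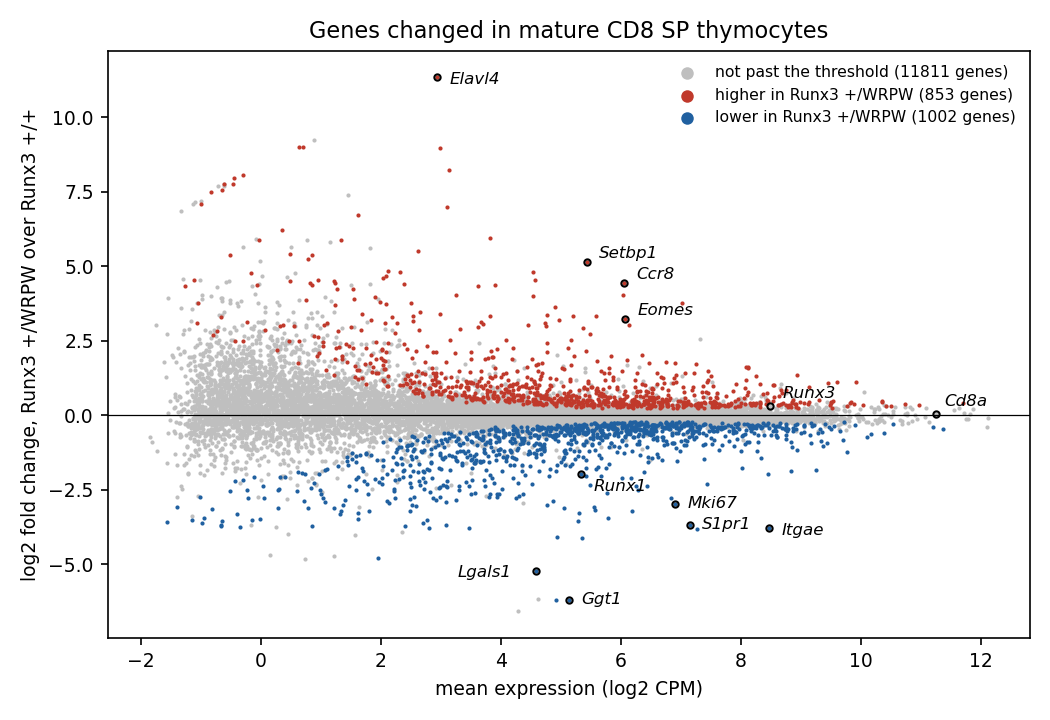
Log2 fold change of Runx3 +/WRPW over Runx3 +/+ against mean expression in log2 CPM for the 13666 genes tested, 1 point per gene, coloured by the edgeR call. The 853 higher genes are in red and the 1002 lower genes in blue, with some genes of the text named; Elavl4, at the top, had 0 counts in both Runx3 +/+ libraries, so its position depends on the prior count of the fit.

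Among the largest rises were transcripts rarely seen in the Runx3 +/+ libraries. Elavl4, a neuronal RNA-binding protein, had 0 counts in Runx3 +/+ and 1054 in Runx3 +/WRPW, where it was at 12.5 ± 4.63 CPM (SD, n = 3), at least 194-fold above a floor of 3 counts over the Runx3 +/+ group. Mmp16, a membrane metalloproteinase, had 1 count against 1051, a ratio of 598 (95% interval 107 to 23658 from the exact conditional binomial). Kcnj15, a potassium channel, had 2 counts against 1271 (ratio 362, 95% interval 100 to 2991), and Fam84a 2 counts against 369 (ratio 105, 95% interval 28.9 to 871). These intervals and the floor cover counting error only. Log2 fold changes were 6.97 for Dmrta1, 5.95 for Elfn2, 5.51 for Evc, 5.14 for Setbp1, 4.84 for Adrbk2, a kinase of G protein-coupled receptors, and 4.8 for Samd3. Setbp1 rose from 2.02 ± 1.11 to 70.2 ± 9.48 CPM and Samd3 from 1.33 ± 0.0976 to 37.4 ± 9.66 CPM.

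The largest falls, beside Itgae, were in genes with clear levels in Runx3 +/+ cells. Ggt1, which encodes gamma-glutamyltransferase, went from 85.9 ± 10.7 to 1.22 ± 0.294 CPM (73.5-fold lower), and Lgals1, which encodes galectin-1, from 57.7 ± 14.4 to 1.49 ± 0.256 CPM (37.4-fold lower). Padi4, a peptidylarginine deiminase, was 74.2-fold lower with Runx3 +/+ libraries at 118 and 29.9 CPM. Log2 changes were -4.78 for Snx9, -4.11 for the tetraspanin gene Tspan32, -4.08 for the cell-cycle factor E2f2, -3.82 for Igfbp4, -3.80 for Depdc1b and -3.79 for Ampd1, an AMP deaminase. Among the changed genes, 62 of the higher and 44 of the lower were predicted gene models or receptor segments, which are not named.

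Cell division genes made up the most uniform group. Of 26 tested members of the cell cycle list, 23 fell, 0 rose and 3 did not pass, and all 26 were lower when adjusted over the list alone. Log2 changes were -2.97 for Mki67, -2.88 for Rrm2, a subunit of ribonucleotide reductase, -2.78 for Top2a, the topoisomerase of mitotic chromosomes, and -2.75 for the spindle protein gene Nusap1. The list's median was -2.12, and camera gave an adjusted p = 2.03e-68, or an adjusted p = 0.0611 with an estimated correlation. The 19 members other than the Mcm genes and Pcna had a median of -2.47, while the other 7, the Mcm genes and Pcna, which act in DNA replication, had a median of -0.35, with 4 of them passing. Without Runx3 +/+ libraries 1 and 2 in turn, 17 and 10 members fell, and 23 without Runx3 +/WRPW library 2.

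Genes of thymocyte maturation and egress fell more often than they rose. Of 19 tested, 8 were lower, 2 higher and 9 did not pass, and adjusted over the list alone 9 were lower and 3 higher. Beside S1pr1, the gene of the integrin chain that pairs with CD103, Itgb7, was 3.61-fold lower. Klf2, a transcription factor that drives S1pr1, was 4.91-fold lower, and Cd52 1.65-fold lower. Ccr7, a homing receptor of naive T cells, was 1.65-fold lower, while Gimap3 was 1.69-fold and the survival gene Bcl2 2.17-fold higher. The median was -0.21, and camera gave an adjusted p = 5.64e-05, or an adjusted p = 0.368 with an estimated correlation. Without Runx3 +/+ library 1, 5 members were lower and 4 higher, and without Runx3 +/+ library 2, 2 were lower and 1 higher. With Runx3 +/WRPW library 2 left out, 8 were lower and 2 higher.

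Naive T cell transcription factors had 5 lower, 0 higher and 7 not passing of 12 tested, with 6 lower when adjusted over the list alone. Lef1, which works with Tcf7 in T cell identity, went from 631 ± 167 to 159 ± 30.4 CPM (3.96-fold lower), Id3 was 4.09-fold lower, and Foxo1, which acts upstream of Klf2, 1.59-fold lower. The median was -0.22, and camera gave an adjusted p = 2.70e-05, or an adjusted p = 0.368 with an estimated correlation. The number lower was 3 without Runx3 +/+ library 1, 1 without Runx3 +/+ library 2 and 5 without Runx3 +/WRPW library 2.

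Genes induced by recent T cell receptor signals were lower in 8 of 16 tested, higher in 1 and not passing in 7, and adjusted over the list alone 11 were lower and 2 higher. Nr4a1, an early response gene of receptor signalling, was 2.51-fold lower, Irf4 2.48-fold lower and Tnfrsf9, which encodes 4-1BB, 1.95-fold lower, while Bcl2l11, which encodes the pro-apoptotic protein BIM, was 2.27-fold higher. The median was -0.62, and camera gave an adjusted p = 2.70e-05, or an adjusted p = 0.150 with an estimated correlation. The number lower was 3 without either of the Runx3 +/+ libraries and 8 without Runx3 +/WRPW library 2.

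Innate-like or memory CD8 genes rose in 4 of 13 tested, fell in 0 and did not pass in 9, and adjusted over the list alone 8 were higher. Beside Eomes, the chemokine receptor gene Cxcr3 went from 3.77 ± 1.57 to 47.0 ± 16.9 CPM (12.3-fold higher), the interleukin-18 receptor subunit Il18rap was 8.80-fold higher, and Id2, an inhibitor of E proteins, 2.24-fold higher. The median was 1.03, and camera gave an adjusted p = 2.70e-05, or an adjusted p = 0.379 with an estimated correlation. The number higher was 1 without Runx3 +/+ library 1, 0 without Runx3 +/+ library 2 and 5 without Runx3 +/WRPW library 2.

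Chemokine receptor and homing genes moved both ways, with 9 lower, 5 higher and 5 not passing of 19 tested, and 10 lower and 6 higher when adjusted over the list alone. Itgae, S1pr1 and Itgb7 had the smallest p-values among the lower genes, and Ccr8 among the higher ones. Cxcr5, the receptor that leads lymphocytes to follicles, was 20.2-fold higher. The median was -0.58 and the mean 0.04, so that they differ in sign. Camera called the list lower with an adjusted p = 0.00947, or an adjusted p = 0.412 with an estimated correlation. That call was lost without Runx3 +/WRPW library 3 (adjusted p = 0.0634) and ranged from 0.00344 to 0.0634 over the fits that left out 1 library. Without Runx3 +/+ library 1, 4 members were lower and 1 higher; without Runx3 +/+ library 2, 3 and 2; without Runx3 +/WRPW library 1, 4 and 5; without Runx3 +/WRPW library 2, 9 and 5.

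Double-positive or immature thymocyte genes fell in 3 of 13 tested, rose in 0 and did not pass in 10, and adjusted over the list alone 4 were lower. Dntt, the terminal transferase of receptor rearrangement, was 3.57-fold lower, the thymic homing receptor Ccr9 1.84-fold lower and Cd81 1.34-fold lower. The median was -0.34, and camera gave an adjusted p = 0.0218, or an adjusted p = 0.368 with an estimated correlation. The number lower was 0 without either of the Runx3 +/+ libraries, 1 without Runx3 +/WRPW library 1, 4 without library 2 and 2 without library 3. The median was -0.53 to -0.16 in these fits.

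**Figure D2:**
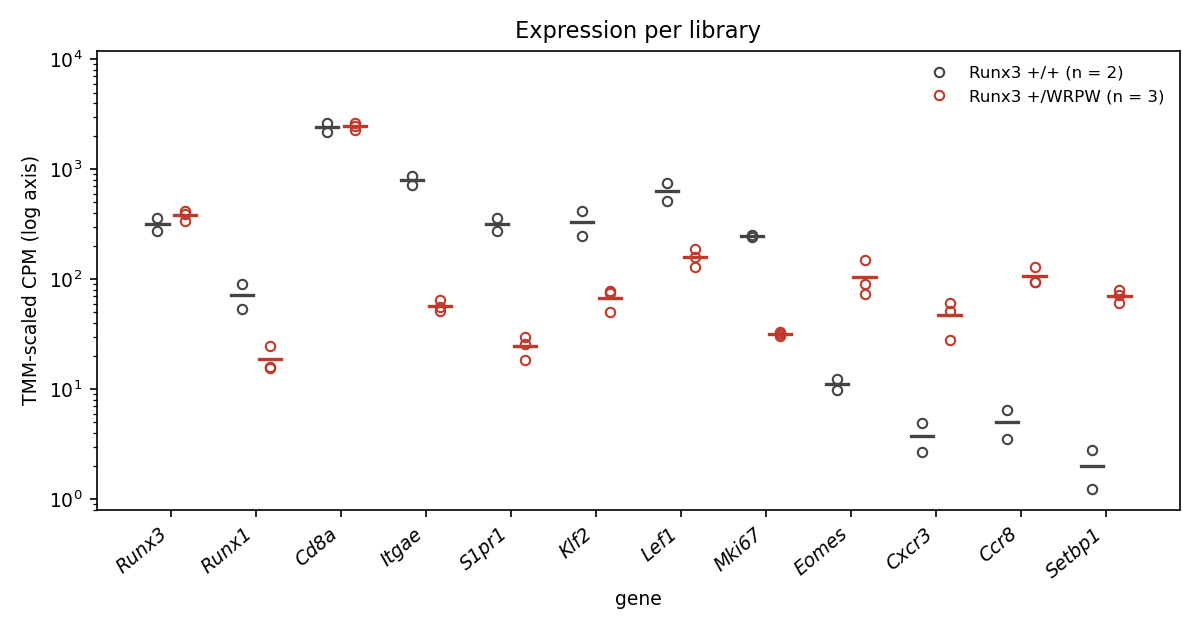
TMM-scaled CPM on a log axis for 12 genes, with 1 circle per library (2 Runx3 +/+ and 3 Runx3 +/WRPW) and a bar at the mean of each genotype. Itgae, S1pr1, Klf2, Lef1 and Mki67 are lower in all 3 Runx3 +/WRPW libraries than in both Runx3 +/+ libraries, Eomes, Cxcr3, Ccr8 and Setbp1 are higher, and Runx3 and Cd8a overlap.

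The coreceptor genes that define the lineage did not pass the test. Cd8a was at 2410 ± 294 CPM in Runx3 +/+ and 2468 ± 186 CPM in Runx3 +/WRPW (log2 difference 0.03 ± 0.10, adjusted p = 0.86), and Cd8b1 had a log2 difference of -0.38 ± 0.19 (adjusted p = 0.253). Cd4 was low throughout, at 0.467 and 5.36 CPM in the Runx3 +/+ libraries and 0.193 ± 0.166 CPM in Runx3 +/WRPW. Its log2 difference of -3.97 ± 1.15, or 15.7-fold lower, was large but uncertain (adjusted p = 0.0743). Zbtb7b, which encodes the CD4 lineage factor ThPOK, was below the count filter, at 0.327 ± 0.0663 and 0.159 ± 0.0810 CPM. Of the 11 CD8 lineage genes tested, 2 were higher (Eomes and Crtam, the latter by 1.80-fold), 2 lower (Itgae and Cd160, the latter by 5.23-fold) and 7 did not pass. Adjusted over the list alone 3 were higher and 3 lower. The list did not pass camera (adjusted p = 0.188, or adjusted p = 0.412 with an estimated correlation), with a median of 0.03 against a mean of -0.38 and a downward test. It did pass when no low-count filter was used (adjusted p = 0.0133). Of 21 cytotoxic effector genes, Crtam and Ctsw (1.43-fold) were higher, the natural killer receptor genes Klrd1 (12.7-fold) and Klrc1 (8.50-fold, from a mean of only 0.667 CPM) were lower and 17 did not pass, with the same numbers adjusted over the list alone. For that list camera gave an adjusted p = 0.794, or an adjusted p = 0.923 with an estimated correlation, and the median of 0.03 stood against a mean of -0.37 and a downward test. Without Runx3 +/+ library 2, 0 CD8 lineage genes were higher and 0 cytotoxic genes changed, and without Runx3 +/+ library 1, 1 CD8 lineage gene was higher and 1 cytotoxic gene moved each way. The cytotoxic list also had 1 gene each way without Runx3 +/WRPW library 1 and 1 lower without library 3, and its test was directed up, without passing, when Runx3 +/+ library 2 or Runx3 +/WRPW library 3 was left out. Without Runx3 +/WRPW library 2, 2 and 2 CD8 lineage genes were higher and lower, and 2 and 4 cytotoxic genes.

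Of 13 CD4 helper lineage genes, 2 rose, the costimulatory receptor gene Cd28 by 1.36-fold and Izumo1r, which encodes folate receptor 4, by 3.08-fold, 0 fell and 11 did not pass. Over the list as a whole, adjusted over the list alone, 3 were higher and 5 lower. Both calls were lost without Runx3 +/WRPW library 2, as they were without library 1 or 3 of that genotype, and that of Cd28 was lost without either of the Runx3 +/+ libraries. The list's median was -0.14, and camera gave an adjusted p = 0.694, or an adjusted p = 0.772 with an estimated correlation. Of 10 regulatory T cell genes, 3 fell, 1 rose and 6 did not pass, and adjusted over the list alone 5 were lower and 2 higher. Foxp3, the factor that specifies regulatory T cells, went from 7.36 ± 3.21 to 0.762 ± 0.393 CPM, Ctla4 was 4.98-fold and Tnfrsf9 1.95-fold lower, and Ikzf4 was 1.74-fold higher. The median was -0.49, camera gave an adjusted p = 0.326, or an adjusted p = 0.667 with an estimated correlation, and 0 of these 4 genes kept a call without either of the Runx3 +/+ libraries. With no low-count filter the list passed camera (adjusted p = 0.0305).

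Of 10 genes of the Runx and Tle families, 2 were lower, 2 higher and 6 did not pass, with 3 and 3 when adjusted over the list alone. Beside Runx1, the corepressor gene Tle3 was 2.01-fold lower, from 295 ± 44.8 to 147 ± 1.65 CPM, while Runx2 was 1.83-fold and Tle4 1.31-fold higher. The median of 0.14 and the mean of -0.06 differ in sign, and camera, directed down, gave an adjusted p = 0.675, or an adjusted p = 0.772 with an estimated correlation. Both rises were lost when Runx3 +/+ library 1, Runx3 +/+ library 2 or Runx3 +/WRPW library 1 was left out, and that of Tle4 also without Runx3 +/WRPW library 3. Of 22 cytokine receptor and Socs genes, 6 were lower, 2 higher and 14 did not pass, with 7 lower and 6 higher when adjusted over the list alone. Il21r was 1.82-fold, Ifngr2 1.48-fold and Il27ra 1.38-fold lower; of the feedback inhibitors, Socs1 was 2.39-fold higher and Socs3 4.07-fold lower. Its median was 0.14 and its mean 0.15 although camera was directed down, with an adjusted p = 0.633, or an adjusted p = 0.785 with an estimated correlation. Without Runx3 +/+ library 1, 2 members were lower and 1 higher, and without Runx3 +/+ library 2, 1 was lower and 0 higher. Leaving out Runx3 +/WRPW libraries 1, 2 and 3 in turn gave 6, 7 and 6 lower and 1, 1 and 4 higher, with the test directed up without library 3 (adjusted p = 0.866).

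Interferon-stimulated genes were lower in 3 of 18 tested, higher in 0 and not passing in 15, with the same numbers adjusted over the list alone. Ifi27l2a was 1.54-fold, Usp18 1.30-fold and Oas1a 1.80-fold lower, the median was -0.20, and camera gave an adjusted p = 0.124, or an adjusted p = 0.667 with an estimated correlation. The camera test passed without Runx3 +/+ library 2 (adjusted p = 0.00058) and without Runx3 +/WRPW library 1 (adjusted p = 0.00905), in a range of 0.00058 to 0.335 over the fits without 1 library. It also passed with no low-count filter (adjusted p = 0.00171). The number lower was 0 without Runx3 +/+ library 1 or Runx3 +/WRPW library 3, and 1 without each of the others. Of 18 immediate-early and heat-shock genes, a class that also responds to cell handling, Klf6 (2.12-fold) and Junb (1.76-fold) were higher, Jund (1.85-fold) and Btg2 (1.67-fold) lower and 14 did not pass, with the same numbers adjusted over the list alone. Its median was 0.07, and camera gave an adjusted p = 0.235, or an adjusted p = 0.772 with an estimated correlation. Without Runx3 +/+ library 2 it passed upward (adjusted p = 0.00631, in a range of 0.00631 to 0.535 over the fits without 1 library), with 1 member higher and 0 lower. Without Runx3 +/+ library 1 it turned downward, with a median of -0.25 (adjusted p = 0.135), 1 member higher and 2 lower, and without library 1 or 3 of Runx3 +/WRPW 1 was lower.

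Most markers of other cell types were low. Of 3 B cell genes tested, Cd79b was 3.88-fold lower, from 7.56 ± 0.00817 to 1.93 ± 0.228 CPM, and 2 did not pass (median -0.42; camera adjusted p = 0.341, or adjusted p = 0.741 with an estimated correlation). Of 5 thymic stroma genes, Pecam1, which T cells also express, was 1.89-fold lower and 4 did not pass (median -0.37; camera adjusted p = 0.339, or adjusted p = 0.609 with an estimated correlation). In both lists the counts were the same when adjusted over the list alone, and 0 members passed without either of the Runx3 +/+ libraries. Without a Runx3 +/+ library further members passed the filter, and the signs of these medians were not stable. Without Runx3 +/+ library 1 they were 1.11 (B cell) and 2.07 (stroma), and without Runx3 +/+ library 2 they were 5.56 and 0.84, over 7 and 9 members tested. Camera passed for neither list there (adjusted p of 0.787 to 0.811). None of 9 myeloid or dendritic cell genes passed in the edgeR test over all genes or adjusted over the list alone, nor with DESeq2 or limma-voom over all genes (median 0.14; camera adjusted p = 0.708, or adjusted p = 0.772 with an estimated correlation). Cst3 was at 44.4 ± 6.55 and 59.4 ± 10.9 CPM and H2-Aa at 0.263 ± 0.0898 and 0.771 ± 0.0758 CPM, at unadjusted p-values of 0.0499 and 0.0304, and the other 7 had none under 0.05. Only 2 natural killer or innate-like T cell genes and 1 erythroid gene could be tested. Klra1 was at 0.257 ± 0.363 and 1.23 ± 1.70 CPM, Sox13 at 0.666 ± 0.414 and 0.698 ± 0.543 CPM, and Alas2 at 0.507 ± 0.188 and 0.543 ± 0.129 CPM, none of them passing.

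**Figure D3:**
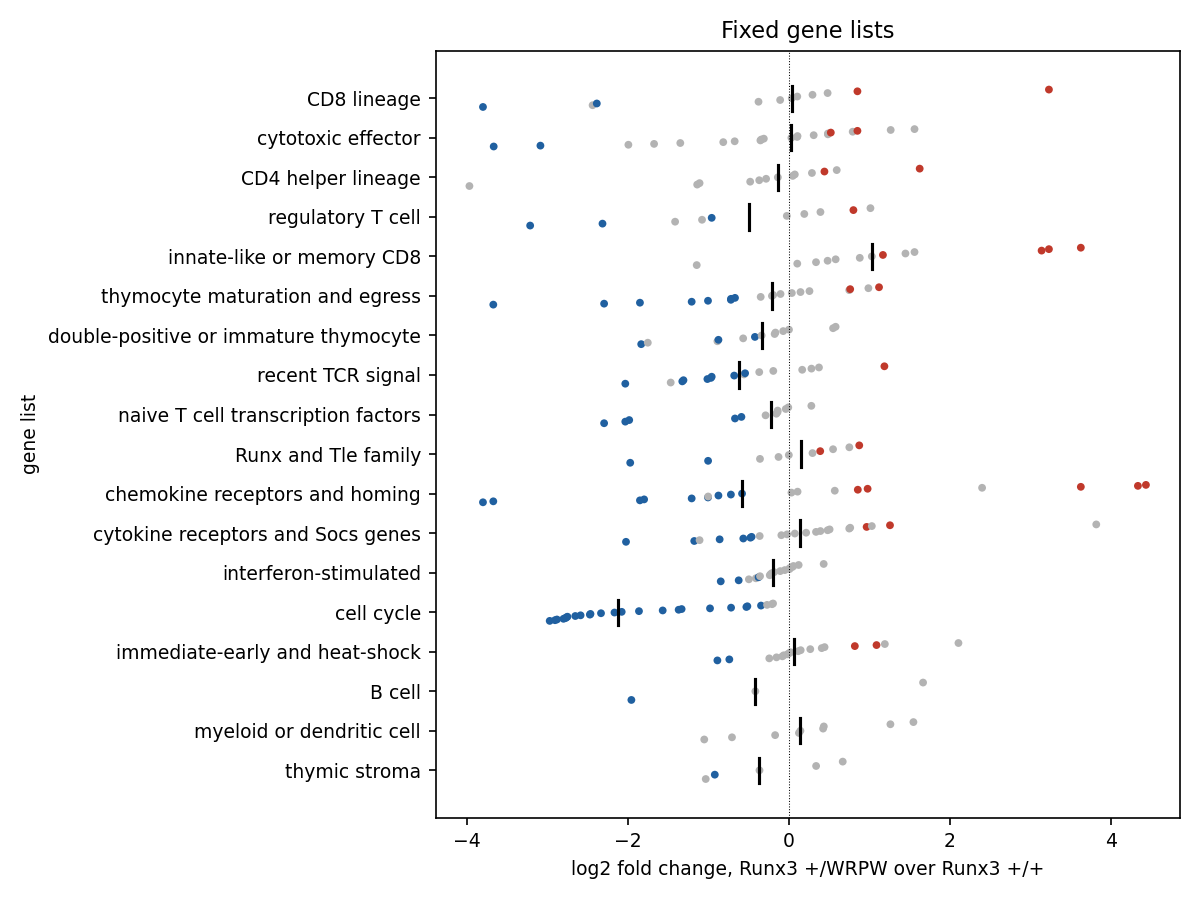
Log2 fold change of Runx3 +/WRPW over Runx3 +/+ for each tested member of the 18 gene lists, 1 point per gene, with red for higher, blue for lower and grey for not past the threshold, and a black bar at the list's median. The cell cycle list has its median at -2.12 with 0 members above zero, and the innate-like or memory CD8 list has its median at 1.03.

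Of the 18 lists tested, camera called 7 with a preset correlation of 0.01 and 0 with an estimated correlation, where the smallest adjusted p was the 0.0611 of the cell cycle list. Several genes stand in more than 1 list, such as Klf2, Id3, Eomes and Itgae, so the lists are not independent. Of the named genes that passed, 16 overlap another counted gene in the annotation, among them Eomes, Elfn2, Foxp3, Cxcr5, Nusap1, Cd160, Ctsw and Ccr9. As the strand setting of the counting is not given in the sources used here, reads of such pairs may not be separable. Klrc1, Klra1 and Gimap3 belong to families of similar genes, whose counts are uncertain for reads shared between copies.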

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

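All alternatives here were chosen in advance. RLE and upper-quartile factors, DESeq2, limma-voom, the stricter filter, robust dispersions and leaving out sex-linked genes gave 1818 to 2705 changed genes, within 1.5 times of 1855; of the calls, 49.0% were lower with upper-quartile factors against 55.1% with RLE. Without a low-count filter 1079 genes changed (442 higher, 637 lower) among 28583 tested, with a median log2 fold change of 0.70 over all genes. Whether the low counts of Runx3 +/WRPW library 2 account for this was not tested. A minimum fold of 1.2 left 866 (354 higher, 512 lower), a stricter question by construction. Leaving out 1 library gave 277 to 1431 changed genes, 106 to 585 higher and 171 to 846 lower, with fewer samples in each fit; the lowest of each was without Runx3 +/+ library 2 and the highest without Runx3 +/WRPW library 2. Every gene called with all libraries kept its sign wherever it was tested, in each of these fits. All 1855 had no overlap between the genotypes, so leaving out a library could hardly turn a sign.

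With the replicate number as a block, 754 genes changed (327 higher, 427 lower), with fewer residual degrees of freedom. Only 2 numbers occur in both genotypes, and the labels do not say that a number marks a shared animal or day, so the samples were not treated as paired. Same-numbered libraries deviated from their group means with correlations of -0.0492 (number 1) and 0.00244 (number 2). The deviations of the 2 Runx3 +/+ libraries mirror each other, so these correlations are weak evidence on pairing. Runx3 stayed short of the threshold in all alternatives, with log2 differences of 0.08 to 0.49. Of the 95 named genes tested, 0 reversed in any alternative, which says little for the called ones, as the genotypes did not overlap there. Calls were lost for 13 with the minimum fold, 19 with the block, 9 without the filter and 5 with limma-voom, and the causes were not tested.

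Of 7 gene lists called, 0 were called with an estimated correlation, a test that by its construction also takes its degrees of freedom from the few libraries instead of the genes. With fry 5 were called, which left out the innate-like and chemokine lists (adjusted p = 0.0751 and 0.0919). Without the low-count filter 10 were called, the added ones being the CD8 lineage (adjusted p = 0.0133), regulatory T cell (0.0305) and interferon-stimulated (0.00171) lists, all downward. Leaving out 1 library gave 6 to 9. The chemokine list was also lost with limma-voom (adjusted p = 0.129) and with the block (adjusted p = 0.370), in a range of 2.91e-06 to 0.412 over its alternatives. Depth limits the low genes, as 3 counts in the shallowest library stand for 0.191 CPM. In simulated data 28.6% of 1.5-fold changes were recovered, over genes of all levels, so that share is no measure of depth.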

Other observations

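The Bcl-2 and TGF-beta superfamily lists, and the tests of sequencing depth, immature thymocytes, less mature cells and natural killer or cytotoxic effector cells, were chosen only after results had been seen; the other tests had been written down before. Receptors of the TGF-beta superfamily and their regulators rose in 7 of 23 tested, fell in 1 and did not pass in 15. Bmpr1a, a type I receptor for bone morphogenetic proteins, went from 0.487 ± 0.16 CPM (SD, n = 2) to 6.62 ± 0.321 CPM (SD, n = 3), a log2 change of 3.74, and the coreceptor Tgfbr3 from 73.9 ± 9.95 to 198 ± 10.7 CPM, a log2 change of 1.42. The others that rose were Ldlrad4, an inhibitor of TGF-beta signalling (1.41), Acvr2a (1.15), the coreceptor Eng (1.13), Bmpr2 (0.70) and Acvr1b (0.60), while the type I receptor gene Acvrl1 fell by 1.46 on the log2 scale. Camera gave p = 0.000104, or p = 0.0403 with an estimated correlation, for a list picked after its genes had been seen, which is no independent evidence of its direction.

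In the Bcl-2 family, 3 of 15 tested genes rose, 1 fell and 11 did not pass. The anti-apoptotic gene Bcl2 went from 455 ± 117 to 989 ± 64.9 CPM, a log2 change of 1.12, and the pro-apoptotic genes Bbc3, which encodes PUMA, and Bcl2l11 rose by 1.99 and 1.18, so genes of opposite action moved the same way. Bak1, a pro-apoptotic effector, fell by 0.37. Camera gave p = 0.122, or p = 0.367 with an estimated correlation.

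Runx3 +/WRPW library 2 had a count at 4479 of 9328 genes that were silent in the other 4 libraries, with 46153 reads in all (0.294% of the library), and no effect of the genotype was tested for this single library. Sequencing depth is argued against, since this is the shallowest library and a deeper one thinned to its total reached at most 17515 genes, 0.639 times as many. Cells of another type would put their reads on their abundant genes, whereas the densest 1% of the silent genes held 6.42% of these reads. That ranking by reads per kb favours short genes, which can hold few reads, so the share is weak evidence. The highest count at any silent gene was 186 of the 46153 reads. Genomic DNA is a candidate explanation: in these male cells, with 1 X chromosome, read density over silent X genes was 0.499 times that over silent autosomal genes (95% bootstrap interval 0.405 to 0.605), and 0.464 times (0.380 to 0.558) when matched on exon length, a match added later. Coverage was not even, however, falling from 6.23 reads per kb in the shortest of 5 exon-length classes to 1.62 in the longest, and silent Y genes, at 0.733 times the autosomal density, had an interval too wide to read (0.025 to 2.17). With the density of each class, the median tested gene would gain 0.475 CPM in this library, and for 6 of 828 genes called higher the background would exceed 25% of the Runx3 +/WRPW mean.

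The lower cell-cycle transcripts in Runx3 +/WRPW could reflect fewer dividing cells among mature CD8 SP thymocytes, as a hypothesis. Immature thymocytes that express Rag genes in the Runx3 +/+ sort are argued against, since Rag1, Rag2 and Ptcra together stood at 0.420 CPM in Runx3 +/+ and 0.626 CPM in Runx3 +/WRPW, although Dntt and Ccr9 did fall. A trend with GC content and exon length was small, moving the median gene by 0.0151, and after its removal the list's median was -2.12, as before. A different mix of dividing and resting SP cells, or of SP stages past Rag expression, in the sort of each genotype stays open, and the expression of these genes per cell cannot be read from bulk counts.

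The lower S1pr1 and Klf2 with higher Eomes and Cxcr3 may reflect another differentiation state of the Runx3 +/WRPW cells, as a hypothesis. Less mature cells in that sort would raise immature thymocyte genes, but these had a median log2 fold change of -0.34, or -0.53 to -0.16 without 1 library, with 0 higher and 3 lower, or 0 lower without either Runx3 +/+ library (camera adjusted p = 0.0218, or adjusted p = 0.368 with an estimated correlation). Natural killer or cytotoxic effector cells are argued against as the source of the gain in Eomes. Such cells would bring granzyme, CC chemokine and killer-receptor transcripts along with their Eomes. The 10 such members of the cytotoxic list together stood at 36.4 CPM in Runx3 +/+ and 10.8 CPM in Runx3 +/WRPW. Divided by the gain in Eomes, that sum was 0.0880 to 0.175 over the Runx3 +/WRPW libraries, with a mean ratio of 0.120. Klrd1 alone went from 18.8 to 1.54 CPM, so the sum does not show that each member fell. Crtam and Ctsw, outside these 10, did rise. Gzmb stood at 0.691, Gzma at 0.32 and Ccl5 at 2.03 CPM in Runx3 +/WRPW. A larger share of memory-like or innate-like CD8 cells low in those transcripts stays open, since bulk counts do not separate it from a change within cells, as do untested differences between the mice other than Runx3.

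Within 10 Mb of Runx3 on chromosome 4, where variants carried along with an edited allele would lie, 27 of 210 tested genes changed (12.9%) against 1812 of 13007 elsewhere (13.9%), an odds ratio of 0.912 (95% interval 0.583 to 1.38; two-sided Fisher's exact test, p = 0.763). The test counts calls and takes no account of their size. Padi4 (74.2-fold lower) and E2f2 (17.0-fold lower), from the 10 largest falls, lie in this window, as do Id3 and Cd52, both lower. An effect of linked variants on such single genes is therefore not excluded. Of the 10 splits of the 5 libraries into 2 and 3, 1 gave as many as 1855 changed genes, the real one, and the highest of the others gave 1. Each of the others mixed the genotypes in at least 1 group, which widens the spread within it, so few calls were likely there. Also, 10 splits are too few for a share under 0.05.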
